A study of Microtus ochrogaster and Microtus pennsylvanicus and Peromyscus californicus with 10 samples.

How the data were processed

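Poly(A) or total RNA was not distinguished in the sources used here: the labels' molecule field reads total RNA, the design text speaks of messenger RNA, and the protocol names a small RNA kit from NEB. The material was fore- and midbrain of reproductive males, and each of the 10 species is represented by 1 library made from a pool of 3 animals. Per the submitters' processing notes, Trimmomatic, BWA and SAMtools were used. Their versions and settings, the reference sequences, the assignment of reads to proteins and the treatment of reads that match several proteins are not given in the sources used here.

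Each library has 1 table of Ensembl protein IDs. Per the file headers it holds raw read counts, which are whole numbers without normalization, and RPM. The RPM values deposited by the authors equal the raw count divided by 1 constant per library and scaled as RPM, and this constant exceeds the sum of the listed counts. The listed IDs therefore hold 89.6% to 99.2% of the reads behind the RPM scale, and the rest is not analysed here. No ID is listed with a count of 0, and the lowest listed count was 1 to 36 depending on the library. An ID that a table lacks was not given a value.

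The labels name species, not mating systems. The groups monogamous and nonmonogamous, and the 5 species pairs (voles, Peromyscus mice, songbirds, poison frogs and cichlids), were set before the data were examined from general knowledge of the species. The monogamous species are Microtus ochrogaster (prairie vole), Peromyscus californicus (California mouse), Anthus spinoletta (water pipit), Ranitomeya imitator (mimic poison frog) and Xenotilapia spiloptera. Their partners are Microtus pennsylvanicus (meadow vole), Peromyscus maniculatus (North American deer mouse), Prunella modularis (dunnock), Oophaga pumilio (strawberry poison frog) and Xenotilapia ornatipinnis. With 1 library per species, the replicate of a mating system is the species, and the animals within a pool cannot be separated.

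The tables share no identifier across all 10 libraries. The 4 rodent libraries use IDs with the prefix ENSRNOP, the songbirds ENSGALP, the frogs ENSXETP and the cichlids ENSONIP. The files pair no ID with a gene name, and 0 of 60949 IDs were matched in the gene table available here. The 39 gene lists fixed beforehand (among them nonapeptide, dopamine, opioid and steroid genes, and markers of brain cell types, pituitary and blood) could therefore not be applied. The planned model over 5 pairs, the gene list tests and the test of rodents against the other clades were not possible either. The mating-system model was fitted to the 4 rodent libraries, and the other clades were described pair by pair. Coordinates and gene annotation were not used here.

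For the rodents, IDs listed in all 4 tables were tested on the raw counts with edgeR 4.0.16 in R 4.3.3. The fit used TMM normalization, filterByExpr, the quasi-likelihood test, the clade as block and Benjamini-Hochberg adjustment at 0.05. This design has 1 residual degree of freedom. The self-test drew counts for 9375 IDs from the rodent means and library sizes, with 200 IDs changed. At the observed biological coefficient of variation (0.83), the test called 0% of IDs changed 4-fold, 4.0% at 16-fold, 42.0% at 64-fold and 90.0% at 256-fold. The simulation gave every ID the same coefficient, and real differences larger than those simulated were not called, so these rates are not the power of the test on the real counts. At a coefficient of 0.2 it called 100% at each of these fold sizes. Log2 CPM values used a prior count of 2. The log2 ratio of a pair is monogamous minus nonmonogamous.

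Within each pair there is no replicate and no test. IDs listed for both partners with at least 10 counts over the pair were compared as TMM log2 CPM ratios, with exact binomial (Clopper-Pearson) 95% intervals that cover counting error only. Intervals on correlations are bootstraps over IDs (1000 draws). IDs are not independent replicates, and these intervals do not cover variation between animals. The fixed rule for named genes required gene symbols. It was applied to IDs instead, limited to the IDs with the largest ratio in each direction among those with at least 50 CPM in 1 library and 10 counts in each. For the rodent test, where no ID passed, the IDs named are the 2 highest and 2 lowest by the smaller of the ratios in both pairs.

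Measures of whole libraries were added after the tables were seen, because they need no shared IDs. They are the RPM constant, the share of reads in listed IDs, the number of listed IDs, the share of the highest ID and of the 10 highest IDs, and the effective number of IDs (the exponential of the Shannon entropy of the counts). Each was compared over 5 pairs by an exact two-sided sign-flip test, whose smallest p is 0.063, and adjusted over the 6 measures.

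Alternatives covered DESeq2 size factors, other count filters, no clade block, DESeq2 1.42.0 and limma-voom (limma 3.58.1) as tests, prior counts, removal of dominant IDs, libraries left out, and unlisted IDs taken as 0. The leave-out of a whole rodent pair leaves no residual degree of freedom and was not run. The alternatives on repeated symbols and on fish gene duplicates had nothing to act on, since each ID occurs once per table and no symbols are given.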

Results

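Brain RNA abundance was measured in 10 vertebrate species that form 5 pairs, each of a monogamous and a related nonmonogamous species. The series title frames the question as whether brain expression profiles tied to monogamy are shared across vertebrates. Every species contributed 1 library from 3 pooled males, giving 5 monogamous and 5 nonmonogamous libraries. The RPM scale of the libraries rested on 36596976 (Oophaga pumilio) to 101971826 (Peromyscus maniculatus) reads, except for 274693175 in Microtus ochrogaster. The tables listed 18547 protein IDs in M. ochrogaster and 13841 in M. pennsylvanicus, and 13167 in P. californicus and 14200 in P. maniculatus. The songbirds had 7327 (Anthus spinoletta) and 8245 (Prunella modularis) IDs, and the frogs 8693 (Ranitomeya imitator) and 7063 (O. pumilio). The cichlids had 18325 (Xenotilapia spiloptera) and 18691 (X. ornatipinnis).

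The comparison that spans all 5 clades was that of how counts were distributed over IDs. Counts were spread more evenly in the monogamous library of each pair. The effective number of IDs, the number of equally abundant IDs that would give the same Shannon entropy, was 2770 ± 1621 in the monogamous and 1723 ± 1444 in the nonmonogamous libraries (SD, n = 5). It was higher in the monogamous partner in 5 of 5 pairs, by a mean of 1047 ± 599 (SD of the differences, n = 5 pairs). The values were 2427 in M. ochrogaster against 1571 in M. pennsylvanicus, and 3248 in P. californicus against 2037 in P. maniculatus. A. spinoletta had 741 and P. modularis 563. The gap was widest in the frogs, with 2261 in R. imitator and 436 in O. pumilio. X. spiloptera had 5175 and X. ornatipinnis 4008.

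The 10 most abundant IDs held a smaller share of the listed counts in the monogamous partner of all 5 pairs. Their share was 14.98% ± 9.18 in the monogamous and 24.79% ± 11.77 in the nonmonogamous libraries (SD, n = 5). In the frogs it was 11.7% in R. imitator and 38.8% in O. pumilio, where a single ID (ENSXETP00000057718) held 12.3% of the counts. Leaving out the frog pair reduced the mean difference in this share from -9.80 to -5.48 percentage points. Both measures gave p = 0.063 in the exact sign-flip test, the smallest value that 5 pairs allow, and 0.188 after adjustment over the 6 measures. Without the pairing, exact permutation of the 10 libraries gave p = 0.302 for the effective number and p = 0.183 for the share of the 10 highest IDs, a test that also takes in the spread between clades. With 5 pairs, the paired test could not have reached 0.05.

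The other 4 library measures had no common direction over the pairs. The number of listed IDs was 13212 ± 5236 in monogamous and 12408 ± 4760 in nonmonogamous libraries (SD, n = 5), and was higher in the monogamous partner in 2 of 5 pairs (exact sign-flip p = 0.625, adjusted p = 0.625). Without the vole pair the mean difference changed from 804 to -172 IDs. The RPM constant was larger in the monogamous partner in 4 of 5 pairs, with a mean difference of 51632298 reads that fell to 14779462 without the vole pair (exact sign-flip p = 0.188, adjusted p = 0.375). The share of reads in listed IDs was higher in the monogamous partner in 2 of 5 pairs (exact sign-flip p = 0.375, adjusted p = 0.450). The share of the highest ID was higher in the monogamous partner in 1 of 5 pairs (exact sign-flip p = 0.312, adjusted p = 0.450).

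**Figure D1:**
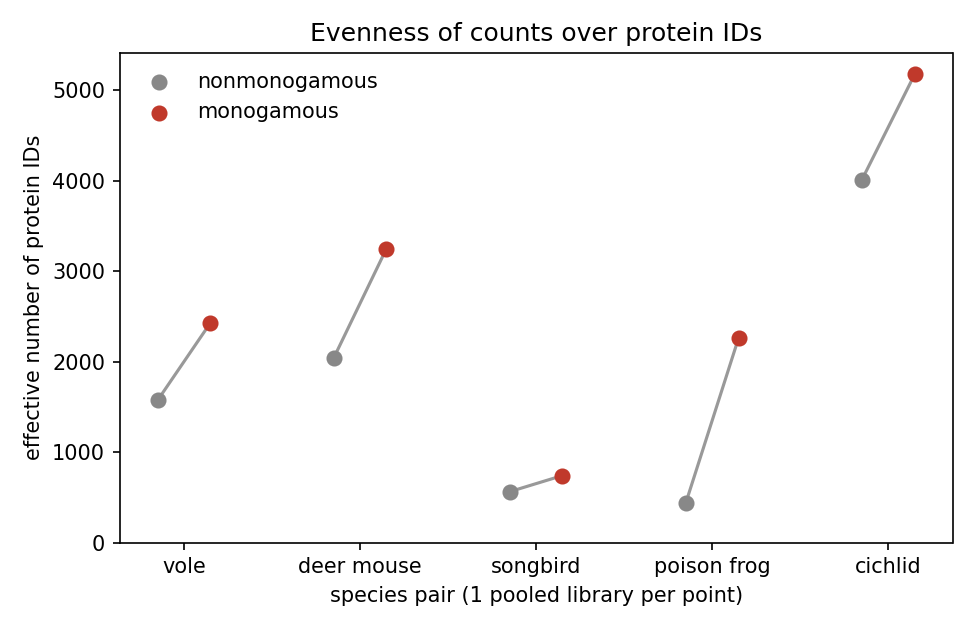
Effective number of protein IDs (linear axis from 0) in each of the 10 pooled libraries, by species pair; grey points are nonmonogamous and red points monogamous species, joined within a pair. The monogamous library lies higher in all 5 pairs, with the widest gap in the poison frogs (2261 against 436) and the smallest in the songbirds (741 against 563).

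In the rodents, where the 4 libraries shared IDs, the test asked which IDs differed with mating system on average over the vole and Peromyscus pairs. No ID passed. Of 9375 IDs tested, 0 were called by edgeR's quasi-likelihood test with the clade as block, and the smallest adjusted p was 0.974. An unadjusted p under 0.05 was found for 232 IDs (161 higher and 71 lower in the monogamous species), where 469 are expected by chance. These numbers depended on the fit and the libraries in it. Without the clade block, 307 IDs (236 higher and 71 lower) had such a p in the 4 libraries, again with 0 called. Leaving out single libraries leaves a lone library in a group. Among these fits, only that without P. californicus had more such IDs than expected by chance, and more of them lower than higher. limma-voom called 0 IDs. DESeq2's Wald test called 288 (210 higher and 78 lower), and called 354 when the mating labels of the Peromyscus pair were exchanged. The biological coefficient of variation was 0.83, and in counts simulated with this spread for every ID the test found 4.0% of 16-fold and 42.0% of 64-fold changes. In the real counts differences larger than any simulated were not called (log2 fold changes of -13.40 and -8.61, given next), so the absence of calls sets no limit on the size of differences.

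Single IDs with large differences in the same direction in both rodent pairs did occur. ENSRNOP00000047954 had 1.90 RPM in M. ochrogaster and 0.400 in P. californicus, against 6831 in M. pennsylvanicus and 10452 in P. maniculatus. Its log2 fold change in edgeR was -13.40 ± 1.62, with an adjusted p of 0.974. The value after ± is an approximate SE, here and for the IDs below. It is the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic, and not a fitted SE from edgeR. ENSRNOP00000027497 had 6.76 and 4.38 RPM in these monogamous species against 2326 and 1531 RPM in their nonmonogamous partners (log2 fold change -8.61 ± 0.53, adjusted p = 0.974 in edgeR). In the other direction, ENSRNOP00000018043 had 247 and 290 RPM in M. ochrogaster and P. californicus, against 0.991 and 0.343 RPM in M. pennsylvanicus and P. maniculatus (log2 fold change 8.66 ± 0.90, adjusted p = 0.974 in edgeR). ENSRNOP00000058920 had 115 and 434 RPM against 0.278 and 3.03 RPM (log2 fold change 7.74 ± 0.89, adjusted p = 0.974 in edgeR). These IDs were picked for the size of their ratios, and the files give no gene names for them.

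Across IDs, the difference between the voles agreed little in direction with that between the Peromyscus mice. The signs matched for 53.2% of IDs, for 57.0% in the third with the highest mean abundance and for 51.8% with the abundance trend of each pair removed. The correlation of the log2 ratios was r = -0.01 (bootstrap over IDs, 95% interval -0.03 to 0.02), with Spearman's rho 0.02. Exchanging the labels in 1 pair, the only other assignment, reverses its sign. More than 2-fold differences in both pairs had the same direction for 1049 IDs (714 higher and 335 lower in the monogamous species) and opposite directions for 1066. Of the opposite IDs, 695 were higher in M. ochrogaster and lower in P. californicus than in their partners, and 371 the reverse. The IDs higher in M. ochrogaster were thus about as often higher (714) as lower (695) in P. californicus. Independent lists of these sizes would share 884 IDs in the same direction and 874 in opposite directions. By direction, 517 would be higher and 367 lower in both monogamous species, so the IDs lower in both were fewer than independent lists would share. Beyond 32-fold, 24 IDs agreed in direction and 20 were opposite, out of 446 such IDs in the voles and 473 in the Peromyscus mice. In the third of IDs with the highest mean abundance, r was 0.06. There 106 IDs had the same direction and 110 opposite directions, against 85 and 82 in independent lists. Of the 106, 40 were higher (27 in independent lists) and 66 lower (58) in the monogamous species. Over all 9375 IDs with the abundance trend of each pair removed, 587 of the IDs that agreed in direction were higher (430 in independent lists) and 431 lower (416). Of the opposite IDs, 562 were then higher and 483 lower in M. ochrogaster.

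**Figure D2:**
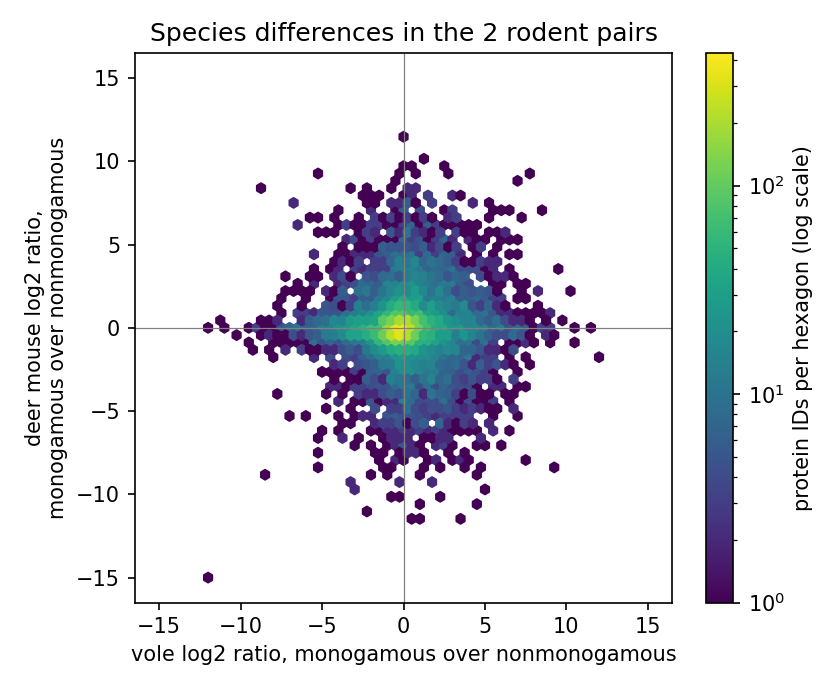
Density of the 9375 protein IDs shared by the rodent libraries, by the log2 CPM ratio (monogamous over nonmonogamous) in the voles (horizontal axis) and in the Peromyscus pair (vertical axis); colour gives IDs per hexagon on a log scale. IDs lie along both axes rather than along a diagonal (r = -0.01), and the isolated hexagon at the lower left holds ENSRNOP00000047954.

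Of the variance of standardised log2 CPM among the 4 rodent libraries, 37.9% lay between voles and Peromyscus mice, 32.2% between mating systems and 29.9% in the remaining contrast. Without standardising each ID, the shares were 37.0%, 31.3% and 31.7%, so the mating-system share was then below the remaining contrast. These contrasts take up all the variance among the 4 libraries, and the mating-system share was below an equal split among them in both cases. With no clade block, the mating-system split gave 307 IDs with an unadjusted p under 0.05 in edgeR, the clade split 571 and the remaining split 342, and each called 0 IDs after adjustment.

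The correlations between rodent libraries did not follow the genera throughout. The highest was between P. californicus and P. maniculatus (r = 0.65 across IDs). M. pennsylvanicus correlated more with P. californicus (r = 0.61) and P. maniculatus (r = 0.60) than with its congener M. ochrogaster (r = 0.56). The lower of the first 2 values exceeded the vole value by 0.03 to 0.07 (bootstrap over IDs, 95% interval). M. ochrogaster had r = 0.52 with each Peromyscus species.

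**Figure D3:**
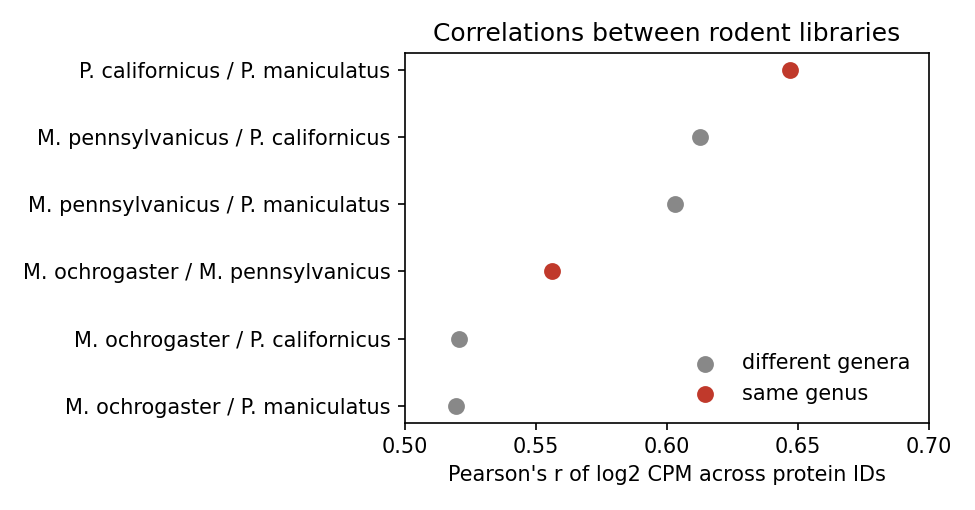
Pearson's r of log2 CPM over 9375 protein IDs for each of the 6 combinations of rodent libraries; red points are species of the same genus and the axis starts at 0.5. The 3 combinations with M. ochrogaster (0.52, 0.52 and 0.56) lie below the 3 without it (0.60, 0.61 and 0.65).

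Within pairs, partner species differed by 2-fold or more at 31.8% to 53.3% of shared IDs. The voles differed most often, at 7032 of 13188 shared IDs (53.3%), followed by the cichlids at 6910 of 15859 (43.6%) and the frogs at 2176 of 5166 (42.1%). The Peromyscus mice differed at 4450 of 11102 (40.1%) and the songbirds at 1944 of 6120 (31.8%). Of these IDs, 57.9% were higher in the monogamous partner in the voles, 54.5% in the Peromyscus mice, 53.1% in the songbirds, 54.0% in the frogs and 52.4% in the cichlids. These shares depended on which IDs entered. Among the 5000 most abundant IDs of each pair they were 34.3% in the voles (578 higher and 1106 lower), 49.6% in the Peromyscus mice, 59.4% in the songbirds, 53.8% in the frogs and 56.0% in the cichlids. With unlisted IDs taken as 0 they were 72.3%, 46.5%, 42.4%, 62.1% and 49.9% in the same order. The order of the pairs changed too, as the frogs differed at 41.1% of the 5000 most abundant IDs and the voles at 33.7%, and with unlisted IDs taken as 0 the frogs differed at 71.7% and the voles at 67.9%. Differences of 32-fold or more were found at 5.1% of IDs in the voles, 5.4% in the Peromyscus mice, 1.8% in the songbirds, 2.0% in the frogs and 3.8% in the cichlids. Among the 5000 most abundant IDs these shares were 2.1%, 1.2%, 1.8%, 1.7% and 0.7% in the same order, and with unlisted IDs taken as 0 they were 33.7%, 29.1%, 31.5%, 50.1% and 21.9%. These are differences between 2 libraries without replicates.

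**Figure D4:**
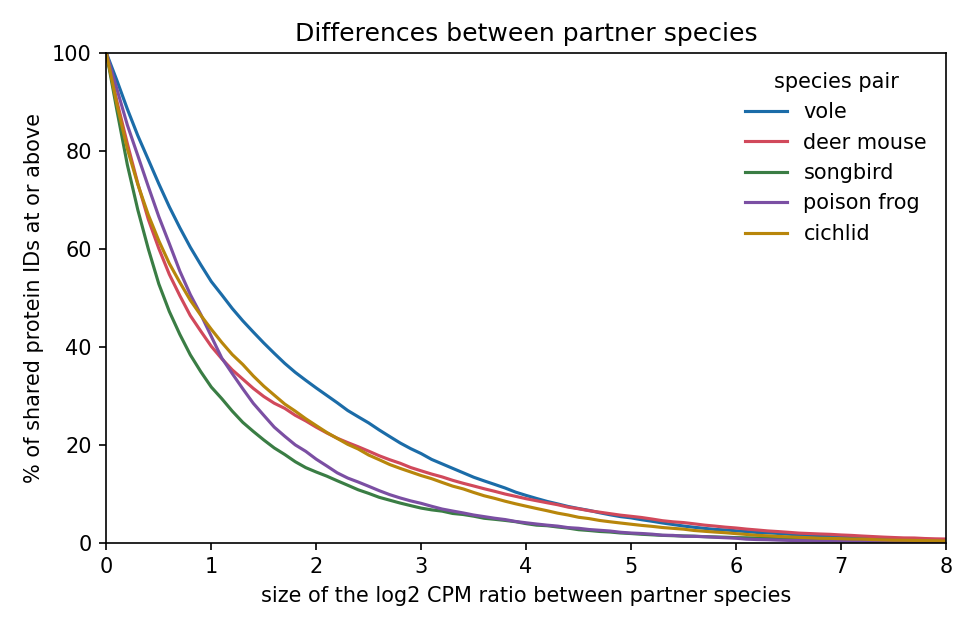
Percentage of protein IDs shared by 2 partner species (vertical axis) whose log2 CPM ratio is at least the size on the horizontal axis, for each of the 5 pairs. At a log2 ratio of 1 (2-fold) the curves lie between 31.8% in the songbirds and 53.3% in the voles.

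Partner libraries correlated at r = 0.78 in the songbirds, 0.68 in the cichlids, 0.67 in the frogs, 0.65 in the Peromyscus mice and 0.59 in the voles (across IDs). The songbirds and the frogs are of different genera and the other 3 pairs each of 1 genus. Which partners were closest depended on the IDs used. With unlisted IDs taken as 0, the 3 pairs of 1 genus had the highest values (0.44 in the cichlids, 0.43 in the voles and 0.36 in the Peromyscus mice, against 0.29 in the songbirds and -0.01 in the frogs). In the third of IDs with the highest mean abundance in each pair, r was 0.61 in the frogs, 0.60 in the Peromyscus mice, 0.54 in the songbirds, 0.51 in the cichlids and 0.45 in the voles.

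The largest single ratios involved some of the most abundant IDs. In the songbirds, ENSGALP00000025508, the most abundant ID of P. modularis, had 151537 RPM there and 7.61 RPM in A. spinoletta, a log2 ratio of -14.26 (counting interval -14.40 to -14.15). In the same pair ENSGALP00000001568 had 3761 RPM in A. spinoletta and 3.96 in P. modularis (log2 ratio 9.89, counting interval 9.69 to 10.12). In the frogs, ENSXETP00000057718 had 115936 RPM in O. pumilio and 501 in R. imitator (log2 ratio -8.13), and ENSXETP00000028143 had 1418 RPM in R. imitator and 1.91 in O. pumilio (log2 ratio 9.23). In the cichlids, ENSONIP00000011818 had 13188 RPM in X. ornatipinnis and 1.65 in X. spiloptera (log2 ratio -13.00), and ENSONIP00000004773 had 880 RPM in X. spiloptera and 0.126 in X. ornatipinnis (log2 ratio 12.46).

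In the voles, ENSRNOP00000067809 had 2911 RPM in M. ochrogaster and 0.674 in M. pennsylvanicus (log2 ratio 11.86), and ENSRNOP00000014312 had 0.433 RPM in M. ochrogaster and 2002 in M. pennsylvanicus (log2 ratio -12.33). In the Peromyscus pair, ENSRNOP00000000658 had 1324 RPM in P. californicus and 0.431 in P. maniculatus (log2 ratio 11.30). The lowest ratio of this pair was that of ENSRNOP00000047954, at -14.81 (counting interval -15.42 to -14.41). How reads that match several protein IDs were counted is not given in the sources used here. Of 17617 entries of at least 100 RPM over the 10 tables, 1343 (7.6%) were not listed for the partner species at all.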

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

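The tests on library evenness, on the vole correlation and on unlisted IDs were chosen only after the patterns were seen, and the test on consecutive ID numbers after its result was seen. No test here can separate a biological explanation from a difference in how each species' table was made, because each species has 1 library and 1 table.

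In the monogamous partner of all 5 pairs the counts were spread more evenly over IDs, the pattern that spans every clade. With every library thinned to 34408019 counts, the mean difference was 1046 effective IDs against 1047 before, in the same direction in 5 of 5 pairs. At these depths thinning barely moves the effective number (2427 to 2426 in M. ochrogaster), so it could not have removed the difference. Only listed counts were thinned, so depth acting through which IDs are listed was not tested. IDs listed for only 1 partner are not the whole cause, since over shared IDs the difference was 738 with 5 of 5 pairs in that direction. A few dominant IDs are not the whole cause either. Without the 10 highest IDs of each library the mean difference was 723, again in 5 of 5 pairs, though the songbird difference was then 72.5 IDs. This removal raised the effective number in every library, to 3135 and 2074 in the frogs (2261 and 436 before) and 2351 and 2278 in the songbirds (741 and 563 before). In relative terms the gap narrowed in every pair, so 723 against 1047 understates the part of dominant IDs. Mating system, RNA quality, dissection and the assignment of reads to IDs stay open, and an exact p of 0.063 is the smallest that 5 pairs can give.

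The M. ochrogaster library stood apart, with 274693175 reads behind its RPM scale, far from the other 4 monogamous libraries (Dixon's test, 1 such result in 12 groups of 5, and chance gives about 1 in 20). The vole correlation stayed below the lower correlation of M. pennsylvanicus with the Peromyscus libraries after thinning (0.56 against 0.60), without IDs over 1% of any library (0.55 against 0.60) and in the third of IDs with the highest mean (0.35 against 0.44). Thinning acted only on IDs listed in all 4 rodent tables, so depth acting through which IDs are listed was not tested. The comparison in the third with the highest mean argues against low counts as the cause of the low vole correlation. Removal of IDs over 1% left 9363 of 9375 IDs. Each ID has equal weight in r, so this removal could hardly have changed it and does not decide on dominant IDs. Reads divided differently among IDs in the M. ochrogaster table would make log ratios of near-identical proteins negatively correlated. Log ratios of IDs with consecutive numbers were uncorrelated in the voles (r = 0.0059), which is not the predicted outcome. Whether consecutive numbers mark near-identical proteins is unknown, so this explanation stays open, as does a real difference between the species.

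Over the 10 libraries, 1343 entries of at least 100 RPM had no entry for the partner species. At their own RPM each would have given at least 3683 reads in the partner, so sampling at equal abundance does not account for them. The cutoff of 100 RPM, with at least 36596976 reads behind each RPM scale, fixed this outcome in advance. Listed IDs with a 64-fold to 1000-fold deficit in the partner numbered 465 in all. Missing IDs outnumbered these in 8 of 10 libraries, and by 962 to 441 without R. imitator, which alone had 381 against 24, but not in M. pennsylvanicus (31 against 65) or X. spiloptera (71 against 74). The prediction was on the sum over libraries, and the split by library was made after its result was seen. An excess of missing over strongly reduced IDs, as in those 8 libraries, can arise where IDs are assigned differently in partner species. Loss of expression in the partner can give it too, was not tested and stays open. The excess also depended on the range. With listed deficits of 16-fold to 64-fold and over 1000-fold included, M. ochrogaster had none (152 missing against 64, 85 and 5 listed). The same held in P. californicus (138 against 68, 79 and 6) and X. ornatipinnis (42 against 52, 35 and 2).

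In the rodents 1066 IDs differed by more than 2-fold in opposite directions in the voles and the Peromyscus mice, and direction alone flagged them. The split that sets M. ochrogaster and P. maniculatus against the other 2 rodents is this contrast. Fitted with the clade as block and without mating system, it called 0 of 9375 IDs, and 279 had an unadjusted p under 0.05, where 469 are expected by chance. A model that holds both contrasts leaves no residual degree of freedom, and the count of 1066 itself was not tested.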

How the results depend on the processing

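The alternatives with unlisted IDs at 0, the third of IDs with the highest mean, the 5000 most abundant IDs, Spearman's rho and removal of IDs over 1% of a library within pairs, trend removal, exchanged labels in DESeq2, single libraries left out, and all those on library measures were added after seeing the data. The rodent test called 0 IDs under each alternative except DESeq2's Wald test (288, with 182 IDs given no adjusted p); for single libraries left out, fitted without the clade block and with the lone library of a group assumed to vary like the others, the count was 0 in each. The low-count filter removed no ID. No paired analysis by replicate number was possible because the labels give none; the clade was the block, and without it the count was also 0. The correlation of rodent pair ratios was 0.0172 as Spearman's rho and 0.0553 in the third of IDs with the highest mean, where the mating-system share was 32.9% and 106 IDs shared a direction, of fewer IDs tested. With unlisted IDs at 0, IDs at 2-fold or more numbered 13042 in the voles, 9582 in the Peromyscus mice, 5266 in the songbirds, 7569 in the frogs and 12200 in the cichlids, and the partner correlations were 0.431, 0.361, 0.286, -0.0122 and 0.437, since absent IDs then count as changed. Among the 5000 most abundant IDs these correlations were 0.443, 0.598, 0.673, 0.645 and 0.515. As Spearman's rho they were 0.704 in the Peromyscus mice, 0.810 in the songbirds and 0.702 in the cichlids. Effective IDs differed by 853 to 1264 with 1 pair left out. The causes of these shifts were otherwise not tested, and DESeq2 size factors, prior counts and stricter filters left each of these counts within 1.5 times its value. The effect of read depth on the rodent test was not tested.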

Other observations

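These values were computed only after the tables were seen. Among IDs with at least 100 RPM in 3 of the rodent libraries, the table of the remaining species had no entry for 19 of 981 IDs (1.9%) in M. ochrogaster, 38 of 857 (4.4%) in M. pennsylvanicus, 28 of 815 (3.4%) in P. californicus and 29 of 892 (3.3%) in P. maniculatus. A further 10, 14, 4 and 13 of these IDs, in the same order, were listed under 1 RPM, and 48, 18, 7 and 15 at 1 to 10 RPM.

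The log2 ratio between partners depended on abundance in some pairs. In the third of shared IDs with the lowest mean abundance, the median ratio (monogamous over nonmonogamous) was 1.29 in the voles, 0.19 in the Peromyscus mice, -0.18 in the songbirds, 0.17 in the frogs and -0.04 in the cichlids. In the third with the highest mean abundance it was -0.25, -0.07, 0.02, -0.06 and -0.02. With this trend removed in both rodent pairs, IDs with more than 2-fold differences numbered 1018 in the same and 1045 in opposite directions, and the correlation of the log ratios stayed at r = -0.01.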
